A study of Mus musculus with 2 samples.

How the data were processed

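The series holds 2 single-cell RNA libraries of immature (CD24-positive) γδ T cells from wild-type C57BL/6 mouse fetal thymus. Per the labels, thymic lobes were taken at embryonic day 15 and kept in culture for 2 days without treatment. The cells were then stained with TMRE, a dye that accumulates in mitochondria according to their membrane potential, and sorted into a bright (TMREhi) and a dim (TMRElo) fraction. Each fraction gave 1 library, made with the 10x Chromium 5′ gene expression kit per the labels.

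The authors deposited, for each library, a matrix of raw UMI counts per gene and barcode. Per the file headers the matrices came from Cell Ranger 3.0.2, and the submitters' processing notes give Cell Ranger 3.0 and genome build mm10. The annotation release and the settings used to call cells are not given in the sources used here. The deposited counts were whole numbers in 1202 TMREhi and 196 TMRElo barcodes. Gene coordinates were taken from GENCODE vM21 on GRCm38, in which 30934 of the 31053 gene identifiers were found.

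Cells were retained when they had at least 500 genes detected and at most 10% of their UMIs from mitochondrial genes. This left 317 TMREhi cells with 2905666 UMIs and 34 TMRElo cells with 105080 UMIs. The limit on mitochondrial UMIs left out 866 TMREhi and 153 TMRElo barcodes, and the limit on genes 177 and 63, with some barcodes failing both. The 5 deepest cells held 4.70% of the retained UMIs in TMREhi and 44.0% in TMRElo. A gene with 3 UMIs stood at 1.03 CPM in TMREhi and at 28.5 in TMRElo, so genes below about that level could not be compared.

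UMIs were summed over the retained cells of each library and expressed as CPM, the customary scaling of counts to an equal library total. Ratios are TMREhi over TMRElo, and log2 ratios were computed after adding 1 CPM to both values. With 1 library per group no test between groups was made and no p-value is given. Intervals on counts are exact Poisson and intervals on shares are exact binomial, at 95%, and hold counting error only. They leave out variation between animals, between sorts and between cells. For a gene with 0 UMIs in 1 library, the ratio is given as "at least" the value against 3 counts in that library. That value is a convention and not a 95% limit. The lower 95% limits in retained cells were smaller, such as 2.51 for Blk and 4.28 for Cd24a.

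The gene lists were fixed before the data were examined: γδ T cell effector programmes, T cell receptor signal, immaturity and maturation, metabolism, cell cycle, stress, and markers of other cell types. For each list the median log2 ratio was taken over members with a mean of at least 10 CPM. That median was placed as a percentile among the medians of 10000 random lists of equal size, drawn from genes in the same of 20 expression bins. Its interval comes from 1000 Poisson redraws of the counts. Named genes followed a rule written in advance. They were 25 genes chosen by name, the 10 largest and 10 smallest ratios among genes with a mean of at least 100 CPM and an interval excluding 1, and up to 4 members per list with a mean of at least 20 CPM. V segments with at least 20 UMIs were also named. Mitochondrial, ribosomal protein, T cell receptor, immunoglobulin, globin and predicted genes were kept out of the ranked part of that rule. Results for 3 genes that the rule names are not reported here.

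Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scanpy 1.11.5, with figures from matplotlib 3.10.9. Doublets were called with Scrublet through scanpy and kept in the comparison, with their removal as an alternative. Cells of both libraries were clustered on 2000 variable genes, 20 principal components and 15 neighbours at Leiden resolution 1, with 0.5 and 2 as alternatives and seed 1 throughout. Phases of the cell cycle were scored on cells thinned to 2099 UMIs, which 266 TMREhi and 15 TMRElo cells reached, with 931 UMIs (286 and 30 cells) as an alternative. The same thinned cells gave the shares of cells with a UMI. The background share of such cells in a type that should lack the gene was not measured.

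The ratios, intervals and list percentiles were tested on simulated data with the depths of the retained libraries and 7802 genes. A 2-fold difference came back as 2.05-fold, with 97 of 100 intervals holding it, and a 4-fold difference as 4.26-fold, with 95 of 100. Of 200 unchanged lists 3% fell outside the central 95% of random lists, and all 50 lists of 2-fold genes stood above the 97.5 percentile. The simulated counts were independent Poisson draws per gene, the same model that the intervals assume, without cells and without genes that vary together. The simulation therefore checks the computation only. It does not show how intervals or percentiles behave where few cells hold the UMIs or list members rise and fall together.

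Alternatives fixed before the data were examined covered all deposited barcodes, a stricter filter (1000 genes, 5% mitochondrial UMIs), doublet removal, removal of other cell types, G1 cells only, per-cell means, thinning, scaling, pseudocount, floors on list members, and counting cells in place of UMIs for V segments. Others were chosen after the counts had been seen. These were a 25% mitochondrial limit, a split of barcodes with at least 500 genes at 15% of UMIs from ribosomal protein genes, the low-ribosomal class without clusters resembling αβ lineage thymocytes, ratios without the top cell, V segments over all deposited barcodes or by barcode class, and clustering of barcodes with at least 500 genes. The rule that named those clusters was also the second tried, since the first named no cluster. It asked for a marker among the top 10 genes, at least 3 markers detected and fewer than 50% of cells with a γ or δ V segment UMI. Summaries of macrophage, globin and Rag1 UMIs by barcode were likewise made after the counts had been seen. Barcodes outside the filter were left out of the comparison of retained cells and appear only where stated.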

Results

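Immature γδ T cells from cultured fetal mouse thymus were sorted by mitochondrial membrane potential into TMREhi and TMRElo fractions and profiled as 1 single-cell library each. There were no replicates, so every difference below is between 2 libraries, and intervals hold counting error only. The retained cells numbered 317 in TMREhi (median 7465 UMIs) and 34 in TMRElo (median 1679 UMIs). The TMRElo values therefore rest on few cells, and 5 of these held 44.0% of the UMIs.

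Both libraries were made up mainly of barcodes with γδ T cell transcripts, but the barcodes fell into 2 classes that were unevenly shared. Among barcodes with at least 500 genes, those with less than 15% of UMIs from ribosomal protein genes made up 733 of 1025 in TMREhi (71.5%, 68.6–74.3) and 117 of 133 in TMRElo (88.0%, 81.2–93.0). Most of these low-ribosomal barcodes exceeded the mitochondrial limit, and among retained cells they were 14.8% (11.1–19.2) of TMREhi and 55.9% (37.9–72.8) of TMRElo. They held 1.80% and 21.0% of the retained UMIs. The remaining high-ribosomal class had 292 TMREhi and 16 TMRElo barcodes, with 54.8% of its TMRElo UMIs in 5 barcodes. Most retained UMIs came from this class, so its values below largely repeat those of retained cells and are not a separate check on them. Clusters named as αβ lineage thymocyte-like made up 261 of the 1025 TMREhi barcodes (25.5%, 22.8–28.2) and 0 of the 133 TMRElo barcodes (interval up to 2.74%). Of these, 159 lay in a cluster led by Rag1 and Cd4. The other 102 lay in a cluster led mainly by cell cycle genes such as Mki67 and Aspm, with the pre-T cell receptor chain gene Ptcra as its only marker among the leading genes and V segment UMIs in 44.1% of barcodes, so its name is less certain. Clustering of the retained cells alone put 39 of 317 TMREhi cells (12.3%, 8.90–16.4) and 2 of 34 TMRElo cells (5.88%, 0.720–19.7) in such a cluster. Rag1, which encodes a subunit of the recombinase that assembles receptor genes, stood at 1037 CPM in the 261 αβ-like barcodes and at 31.0 CPM in the other low-ribosomal TMREhi barcodes. Because of this, key results are also given for low-ribosomal barcodes without the αβ-like clusters, 476 in TMREhi and 117 in TMRElo, a set that also leaves out those cycling barcodes.

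**Figure D1:**
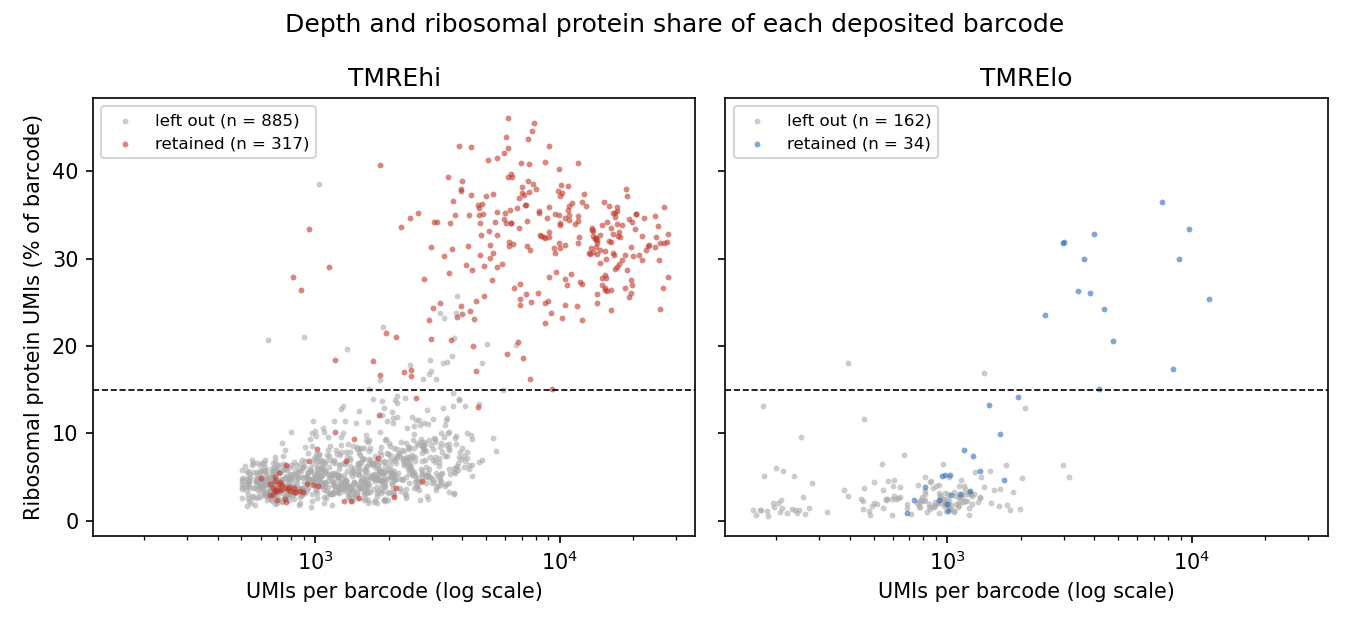
UMIs per barcode (log scale) against the percentage of UMIs from ribosomal protein genes, for all deposited barcodes of each library, with retained cells coloured and the 15% split dashed. Low-ribosomal barcodes were the larger class in both libraries and mostly fell outside the filter.

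Genes of the IL-17-producing γδ T cell programme were higher in TMREhi. Maf, a transcription factor required for γδ T cells that make IL-17, stood at 130 CPM against 28.5 CPM (3 UMIs), a ratio of 4.57 (1.55–22.3). Blk, a kinase needed for these cells, had 258 UMIs in TMREhi and 0 in TMRElo, at least 3.11-fold. Sox13, another factor of this lineage, had a ratio of 5.10 (0.900–203) on 1 TMRElo UMI. Of 21 members 14 were higher and 7 lower, with a median log2 ratio of 1.09 (0.68 to 2.32) at the 100 percentile of matched random lists. With the 4 members that had 0 UMIs in 1 library set at their bound, the median was 0.97. Among the higher members only Sox4, a factor needed with Sox13 in these cells, had more than 3 TMRElo UMIs (474 against 8 UMIs). Thinned to equal depth, 24.4% of TMREhi cells (19.4–30.1) and 0 of 15 TMRElo cells (interval up to 21.8%) held a Maf UMI. Thinned further to keep 30 TMRElo cells, the shares were 17.5% (13.3–22.4) and 6.67% (0.818–22.1), and the background share in cells that should lack Maf was not measured. Cd44, an adhesion receptor, was the lowest member at 12.7 against 66.6 CPM (5.23-fold higher in TMRElo, 1.97–11.9), with 85.7% of its 7 TMRElo UMIs in 1 cell and a log2 ratio of 0.27 without the top cells. Rora, which encodes a nuclear receptor of this programme, stood at 41.0 against 76.1 CPM, and Il7r, the interleukin 7 receptor chain, at 186 against 266 CPM, with intervals that held 1. Il17a itself had 22 UMIs in TMREhi and 0 in TMRElo, at or below the floor for a ratio.

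The difference in this programme was larger among low-ribosomal barcodes without the αβ-like clusters. There 22 of 25 members were higher in TMREhi, with a median log2 ratio of 2.48 (1.69 to 3.25), or 1.36 with 7 members at their bound. Maf stood at 335 against 59.3 CPM (5.66-fold, 2.83–13.2), Sox13 at 158 against 14.8 CPM (10.6-fold, 2.89–88.7), and Blk had 139 UMIs against 0 (at least 7.46-fold). Among high-ribosomal barcodes the median was 1.78, with 16 of 21 members higher, and 0.76 with members at their bound. Restricting the list to members of at least 50 CPM gave a median of 0.33, and in G1 cells, where 20 of 26 members had 0 UMIs in 1 library, the median with bounds was 0.00477.

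Use of V segments also differed, with the fetal Vδ1 chain more frequent in TMREhi. Trdv4, the segment for Vδ1, was the most abundant δ segment in 204 of 500 TMREhi barcodes with a δ segment (40.8%, 36.5–45.3) and in 4 of 52 TMRElo barcodes (7.69%, 2.14–18.5). Tcrg-V6, the Vγ6 segment whose chain pairs with Vδ1 in the IL-17-producing fetal wave, led in 125 of 727 (17.2%, 14.5–20.1) and 2 of 123 (1.63%, 0.198–5.75). Counted as UMIs in retained cells the gap was smaller, at 8.16% (7.31–9.09) against 5.49% (2.67–9.87). All 10 of these TMRElo Tcrg-V6 UMIs lay in 1 of 34 cells, against 59 of 317 TMREhi cells with such a UMI. Tcrg-V5, the segment of the Vγ5 chain of epidermal γδ T cells, led in 6.74% and 1.63% of barcodes but held 2.97% (2.45–3.57) and 3.30% (1.22–7.04) of γ UMIs in retained cells. Trdv2-2 was the leading δ segment in 38.4% (34.1–42.8) of TMREhi and 57.7% (43.2–71.3) of TMRElo barcodes, and Tcrg-V4 the leading γ segment in 18.8% (16.1–21.9) and 27.6% (19.96–36.4). Trgv2, nearly identical in sequence to Tcrg-V1 and Tcrg-V3 so that reads may be shared among them, led in 47.3% and 52.8%. Counted as UMIs in retained cells, Trdv4 held 54.8% (52.1–57.5) against 3.03% (1 of 33 UMIs). Counted as UMIs over all deposited barcodes it held 33.6% in TMRElo, of which 76.7% lay in 1 barcode. Among UMIs of high-ribosomal barcodes, Trdv4 held 55.3% (52.6–57.9) in TMREhi and 8.70% (1.07–28.0) in TMRElo. There Tcrg-V6 held 7.97% (7.13–8.88) and 6.80% (3.31–12.2), and Tcrg-V4 14.6% (13.5–15.8) and 15.0% (9.62–21.8), with overlapping intervals. The TMRElo value for Tcrg-V6 again came from 1 barcode with 10 UMIs, so its interval does not describe spread between cells.

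**Figure D2:**
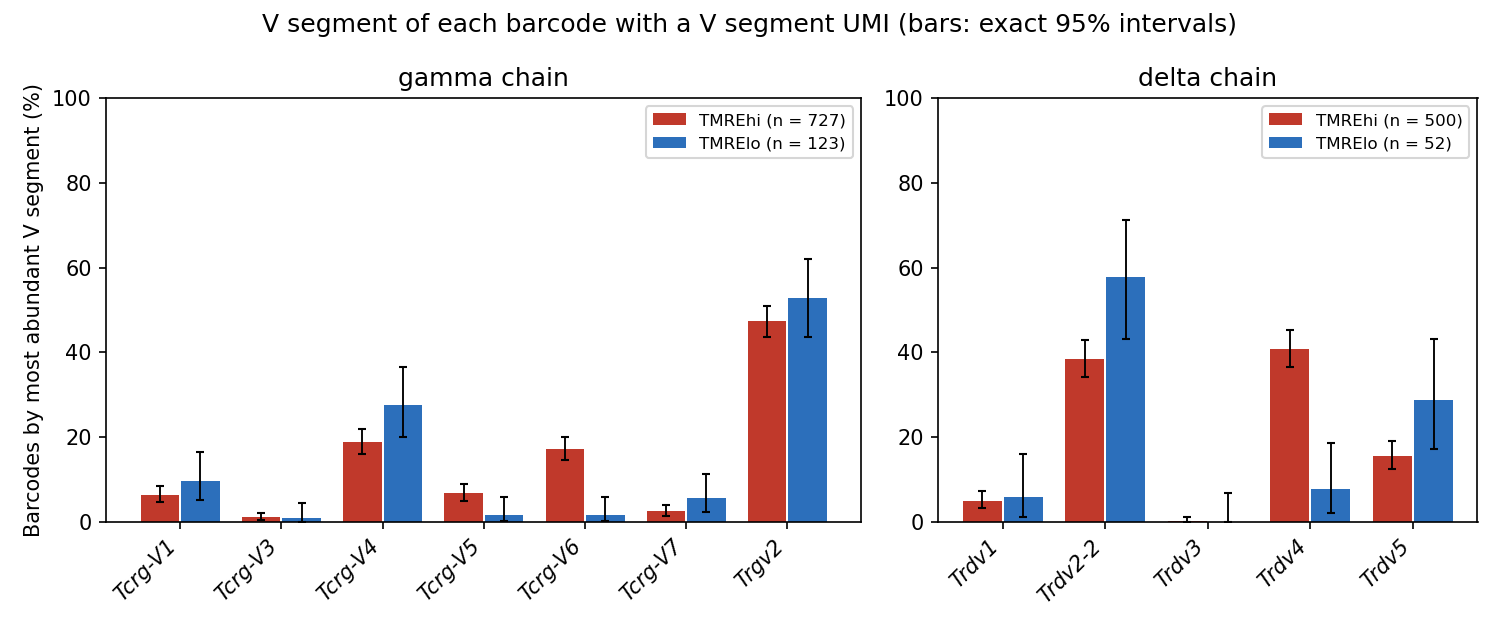
Percentage of barcodes by their most abundant γ (left) and δ (right) V segment in TMREhi and TMRElo, over all deposited barcodes, with exact binomial 95% intervals. Trdv4 and Tcrg-V6 took a larger share in TMREhi, and Trdv2-2 and Tcrg-V4 a larger share in TMRElo.

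Genes of the IFN-γ-producing and cytotoxic programme were mostly lower in TMREhi among retained cells. Il2rb, the receptor chain for interleukins 2 and 15, stood at 53.3 against 314 CPM, 5.89-fold higher in TMRElo (3.91–8.62). Stat4, which transmits interleukin 12 signals, stood at 37.5 against 295 CPM, 7.86-fold higher in TMRElo (5.10–11.8). Xcl1, a chemokine of cytotoxic lymphocytes, was 37.97-fold higher in TMRElo (32.4–44.5; 94.99 against 3607 CPM), with 73.6% of its TMRElo UMIs in 1 cell. All 379 TMRElo UMIs lay in 5 cells, and it was 12.1-fold higher in TMRElo without the top cell of each library. In G1 cells Xcl1 was higher in TMREhi instead (157 against 1 UMIs; interval of the ratio 1.50–337). Gzmb and Gzmc, which encode granzymes, were 23.5-fold and 60.2-fold higher in TMRElo, with 81.0% and 59.5% of TMRElo UMIs in 1 cell. Gzma, another granzyme gene, went the other way at 1793 against 85.7 CPM (20.9-fold higher in TMREhi, 11.02–45.8). Of 19 members 2 were higher and 17 lower, with a median log2 ratio of −1.99 (−2.40 to −1.86) at the 0 percentile. Neither Ifng (0 UMIs in both) nor Tbx21, which encodes the factor T-bet (7 UMIs against 0), could be compared.

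This list difference was not seen among low-ribosomal barcodes without the αβ-like clusters. There the median was −0.10 (−0.42 to 0.18), against −0.65 (−0.90 to −0.31) with those clusters included, the mean 0.11 with the opposite sign, and 8 members were higher and 11 lower. Stat4 at 199 against 489 CPM (2.45-fold higher in TMRElo, 1.82–3.28) and Xcl1 at 289 against 726 CPM (2.51-fold, 1.97–3.19) kept their direction, as did Gzma at 1426 against 74.1 CPM (19.3-fold higher in TMREhi, 10.4–40.2). Gzmb did not keep its direction (76.4 against 51.9 CPM; 1.47, 0.675–3.81). Il2rb stood at 172 against 230 CPM (1.34-fold higher in TMRElo, 0.876–1.98). In the 98 and 8 retained cells called G1 the list median was −0.08. Among high-ribosomal barcodes, by contrast, 17 of 19 members were lower in TMREhi, with a median of −2.26 (−2.51 to −2.03).

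**Figure D3:**
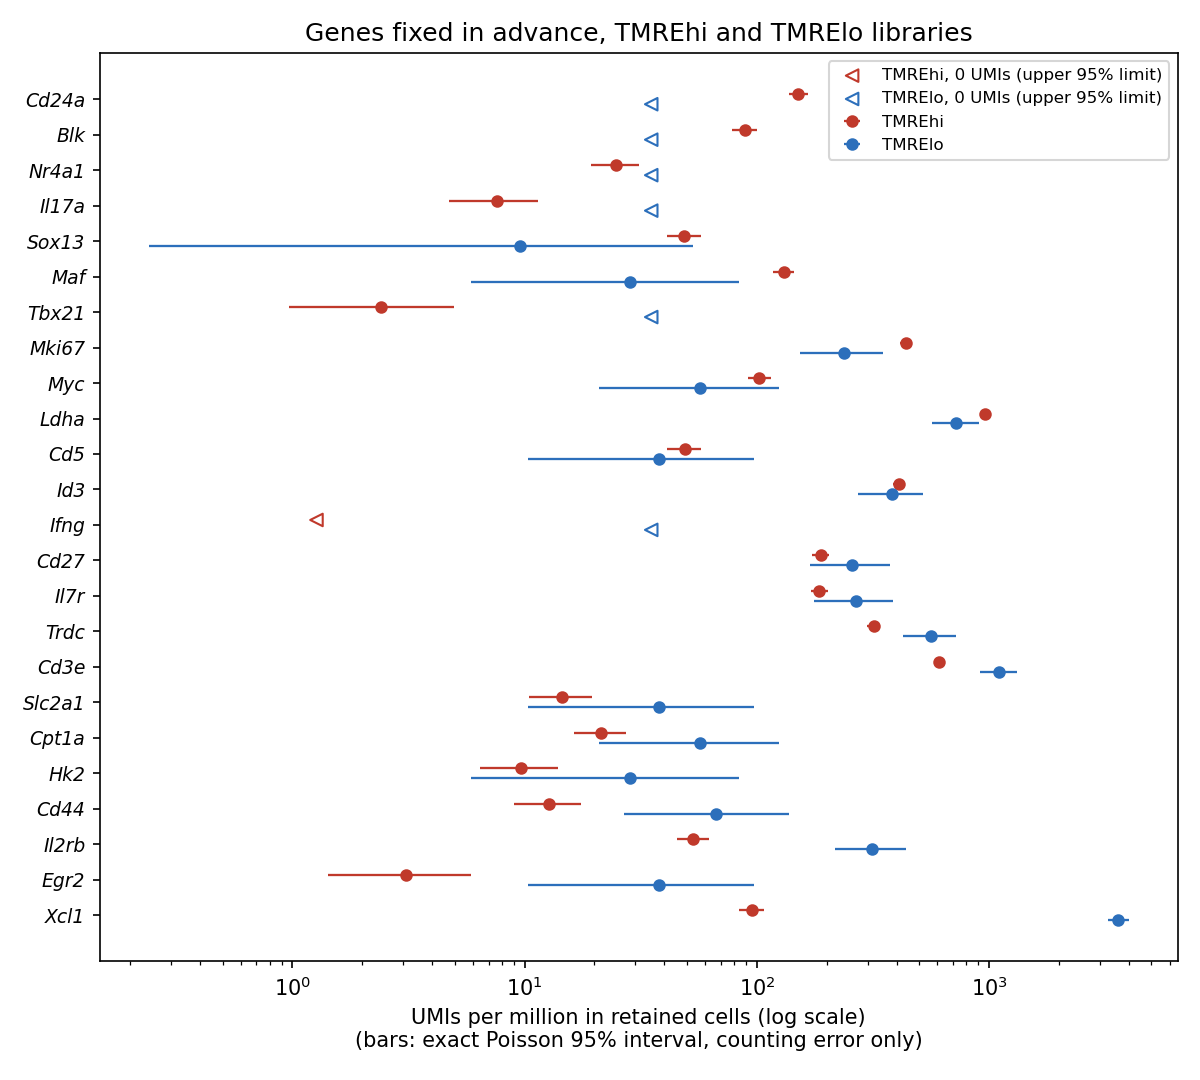
CPM (log scale) of 24 genes fixed in advance in retained TMREhi and TMRElo cells, with exact Poisson 95% intervals and triangles at the upper limit where no UMI was counted. Cd24a, Blk and Maf stood higher in TMREhi, and Xcl1, Il2rb and Egr2 higher in TMRElo.

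Genes of thymocyte maturation and exit were mostly lower in TMREhi, while the surface marker of immaturity was higher. S1pr1, the receptor that T cells use to leave the thymus, stood at 26.2 against 219 CPM (8.37-fold higher in TMRElo, 5.01–13.5; 5.29-fold, 2.53–10.04, among high-ribosomal barcodes). A cluster led by Tdrp, with S1pr1 and Foxo1 among its top 10 genes, held 21 of 34 TMRElo and 19 of 317 TMREhi retained cells. Its cells were shallow (median 1223 UMIs), and depth and barcode class were not separated from maturation there. Foxo1, a factor that drives S1pr1 expression, stood at 30.3 against 276 CPM (9.11-fold higher in TMRElo, 5.77–14.01; 4.23-fold, 2.04–7.94, among high-ribosomal barcodes), and Gimap3, a lymphocyte survival gene, at 47.5 against 247 CPM (5.21-fold, 3.29–7.96). Of 23 members 3 were higher and 20 lower, with a median log2 ratio of −1.16 (−1.38 to −0.88) at the 0 percentile. In G1 cells, of which TMRElo had 8, the median was −0.26 (−0.55 to −0.04) at the 20.9 percentile, with 8 members higher and 15 lower. Cd24a, which encodes the immaturity marker used in the sort, had 438 UMIs in TMREhi and 0 in TMRElo, at least 5.28-fold. Both fractions, however, were sorted as CD24-positive. Thinned to equal depth, 17.7% of TMREhi cells (13.3–22.8) and 0 of 15 TMRElo cells (interval up to 21.8%) held a Cd24a UMI. At 931 UMIs the shares were 8.74% (5.74–12.6) and 0 of 30 (interval up to 11.6%), so these intervals overlapped. In the low-ribosomal class, 1 of 2 thinned TMRElo barcodes held a Cd24a UMI. The immature thymocyte list, which includes Rag1, had a median of −0.25 (−0.51 to 0.23) at the 49.4 percentile. It was 0.44 (−0.15 to 1.05) among high-ribosomal and 0.57 (0.34 to 1.04) among low-ribosomal barcodes. Once the αβ-like clusters were left out, the low-ribosomal median of this list was −0.39 (−0.47 to 0.11), with 6 members higher and 10 lower. Among low-ribosomal barcodes without αβ-like clusters the maturation median was −0.12 (−0.31 to 0.14), against −0.70 (−0.86 to −0.36) in the low-ribosomal class as a whole and −1.04 (−1.23 to −0.90) among high-ribosomal barcodes, while S1pr1 (148 against 548 CPM, 3.70-fold higher in TMRElo, 2.74–4.98) and Foxo1 (113 against 400 CPM, 3.53-fold, 2.48–4.98) kept their direction.

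Genes of receptor signalling were mixed in direction. Egr2, induced by strong receptor signals, stood at 3.10 against 38.1 CPM (4 TMRElo UMIs; 12.3-fold higher in TMRElo, 2.77–44.0), and Nr4a1, another such gene, had 72 UMIs against 0, below the floor for a ratio. Id3, a γδ lineage gene downstream of the receptor, was 408 against 381 CPM (1.07, 0.782–1.51), and Cd5, whose surface level follows signal strength, 48.9 against 38.1 CPM (1.28, 0.491–4.78). Pdcd1, the inhibitory receptor PD-1, was higher in TMREhi at 117 against 19.0 CPM (2 UMIs; 6.17-fold, 1.69–51.1). The list had 8 members higher and 12 lower, with a median log2 ratio of −0.48 (−0.90 to 0.19) at the 31.8 percentile. Over all deposited barcodes 15 of 22 members were lower, with a median of −0.76 (−1.01 to −0.35) at the 2.09 percentile, and among high-ribosomal barcodes the median was −0.65 (−1.01 to 0.02). The receptor genes Trdc (319 against 561 CPM; 1.76-fold higher in TMRElo, 1.33–2.29) and Cd3e (606 against 1104 CPM; 1.82-fold, 1.50–2.20) were lower in TMREhi.

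Nuclear genes for subunits of oxidative phosphorylation were higher in TMREhi. Uqcrq, a complex III subunit, stood at 599 against 181 CPM (3.31-fold, 2.11–5.51), and Atp5o, an ATP synthase subunit, at 383 against 114 CPM (3.35-fold, 1.91–6.51). Ndufa13, a complex I subunit, was lower at 371 against 476 CPM. Of 76 members 71 were higher and 5 lower, with a median log2 ratio of 0.51 (0.43 to 0.63) at the 100 percentile. The median was 0.88 (0.70 to 1.07) among low-ribosomal barcodes without αβ-like clusters, 0.27 (0.21 to 0.44) among high-ribosomal barcodes and 0.11 in G1 cells, of which TMRElo had 8. Genes of the mitochondrial ribosome and import (83 higher, 24 lower; median 0.33, 0.31 to 0.62) and of the TCA cycle (14 higher, 6 lower; median 0.49, 0.11 to 0.84) were also mostly higher.

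The mRNAs encoded by mitochondrial DNA went the other way in retained cells, with 1 of 13 higher and a median of −0.43 (−0.54 to −0.34). They included mt-Atp6, an ATP synthase subunit, at 5362 against 8746 CPM. All mitochondrial UMIs made up 3.65% (3.63–3.68) of TMREhi and 5.04% (4.90–5.17) of TMRElo. This direction depended on the barcodes kept, since among low-ribosomal barcodes without αβ-like clusters all 13 were higher in TMREhi (median 0.34, 0.28 to 0.38), and the stricter filter gave shares of 3.27% and 3.25%.

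Other metabolic lists had medians closer to equality. The median gene of at least 50 CPM stood at a log2 ratio of −0.20, so a list near equality was not an average list. Percentiles among random lists were 98.7 for cholesterol synthesis, 92.9 for fatty acid oxidation and 87 for amino acid genes. Glycolysis had 11 members higher and 8 lower (median 0.09, −0.14 to 0.47; 66.1 percentile). Ldha, which makes lactate from pyruvate, was 959 against 723 CPM (1.33, 1.06–1.69), whereas Pfkp, a phosphofructokinase, was 3.34-fold higher in TMRElo (1.61–6.27; 31.3 against 105 CPM). The glucose transporter gene Slc2a1 (14.5 against 38.1 CPM) and the hexokinase gene Hk2 (9.64 against 28.5 CPM) had few TMRElo UMIs. Fatty acid oxidation genes split evenly (9 and 9; median 0.03, −0.23 to 0.71), with Cpt1a, which carries fatty acids into mitochondria, at 21.3 against 57.1 CPM (2.68-fold higher in TMRElo, 0.946–6.16). Amino acid genes also split evenly (9 and 9; median 0.03), with Phgdh, of serine synthesis, 2.03-fold higher in TMREhi (1.12–4.08) and Slc1a5, a neutral amino acid transporter, 2.48-fold higher in TMRElo (1.25–4.47). Cholesterol synthesis had a median of 0.28 (−0.25 to 0.63) in retained cells and 0.66 (0.46 to 1.27) in low-ribosomal barcodes without αβ-like clusters.

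**Figure D4:**
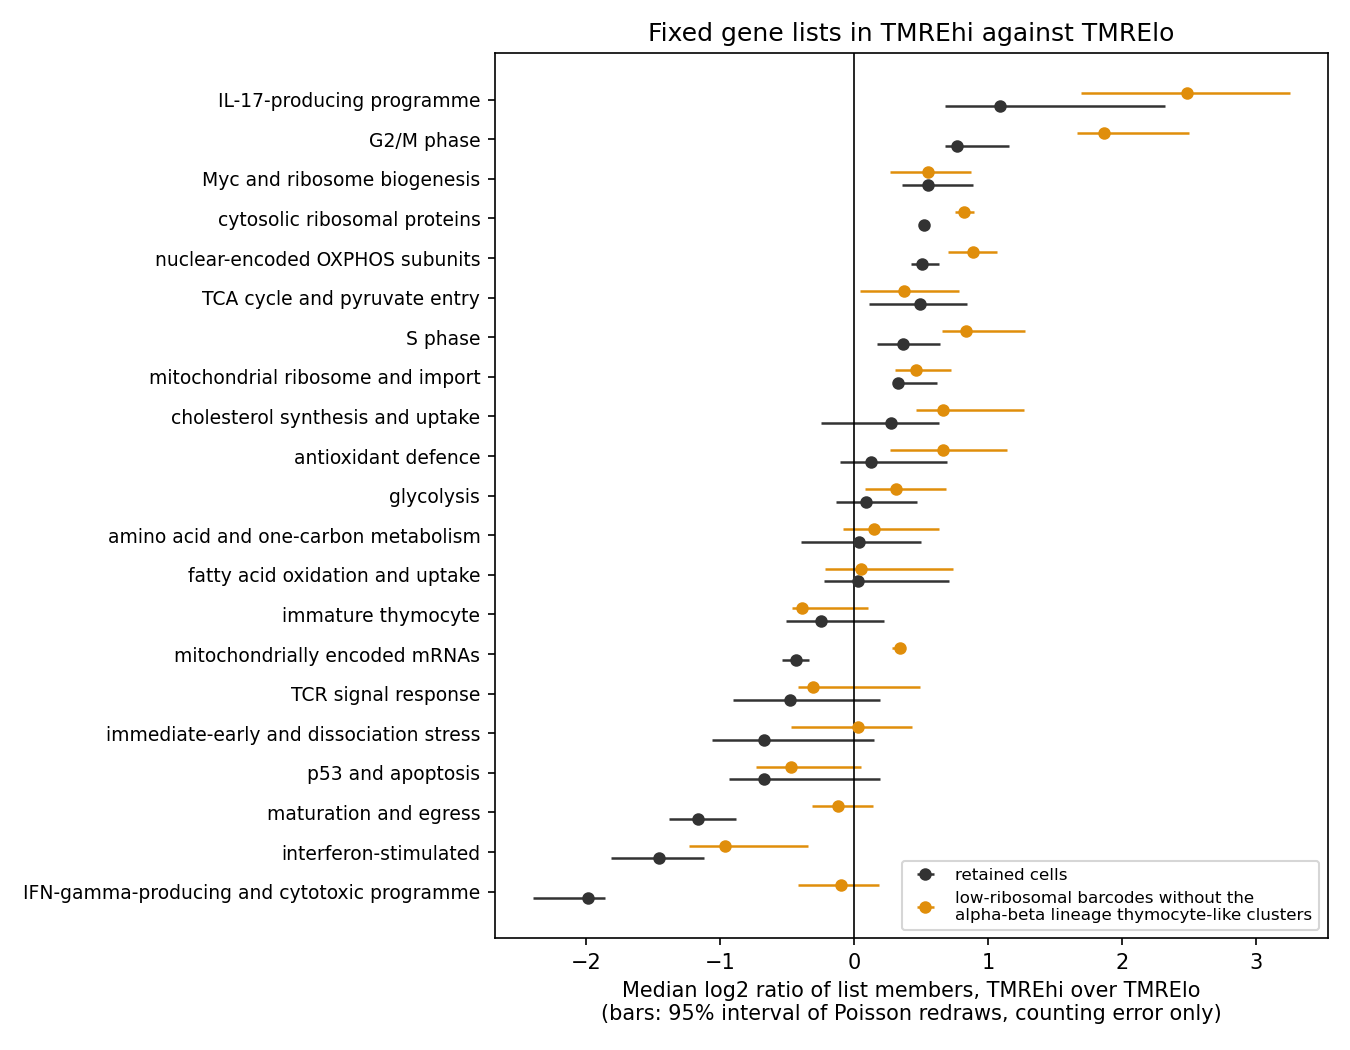
Median log2 ratio (TMREhi over TMRElo) of each gene list in retained cells (black) and in low-ribosomal barcodes without αβ-like clusters (orange), with 95% intervals from Poisson redraws. The IL-17, G2/M and oxidative phosphorylation lists lay above 0 in both sets, and the interferon-stimulated list below 0 in both.

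Proliferation genes were higher in TMREhi. Ube2c, which drives exit from mitosis, stood at 525 against 57.1 CPM (9.20-fold, 4.22–25.1), and Mki67, the Ki-67 gene, at 437 against 238 CPM (1.84-fold, 1.24–2.85). The mitotic genes Cdc20 and Hmmr had 268 and 295 UMIs in TMREhi and 0 in TMRElo, at least 3.23-fold and 3.56-fold. Of 50 G2/M genes 45 were higher and 5 lower, with a median log2 ratio of 0.77 (0.68 to 1.16) at the 100 percentile. The S phase list had 29 higher and 11 lower (median 0.36, 0.17 to 0.64), though the stricter filter gave −0.08 for this list and 0.21 for G2/M. Among high-ribosomal barcodes the S phase median was 0.11 (−0.08 to 0.44). Targets of Myc, a transcription factor of cell growth, had 20 members higher and 5 lower (median 0.55, 0.36 to 0.89), while Myc was 103 against 57.1 CPM (1.80, 0.816–4.93). At equal depth, 63.2% (57.1–69.0) of TMREhi and 7 of 15 TMRElo cells (46.7%, 21.3–73.4) were called S or G2/M. Thinning to 931 UMIs, which left 30 TMRElo cells, gave 63.3% (57.4–68.9) and 26.7% (12.3–45.9). Cytosolic ribosomal protein genes were higher as well, with 78 members higher and 5 lower (median 0.52, 0.49 to 0.56). The median was 0.28 (0.25 to 0.33; 70 higher, 13 lower) among high-ribosomal barcodes and 0.28 (0.22 to 0.33; 68 higher, 15 lower) in G1 cells.

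Among stress genes, those induced by interferon were lower in TMREhi. Irf7, a factor that amplifies interferon responses, stood at 14.1 against 76.1 CPM (5.40-fold higher in TMRElo, 2.18–11.7), and Ifit1, an antiviral gene, at 8.26 against 38.1 CPM (4.61-fold, 1.16–13.4). Of 13 members 1 was higher and 12 lower, with a median log2 ratio of −1.45 (−1.82 to −1.12). The median was −0.96 (−1.23 to −0.34) in low-ribosomal barcodes without αβ-like clusters and −0.07 in G1 cells. The peroxide-reducing enzymes Prdx1 (2.63-fold, 1.86–3.85) and Prdx2 (2.64-fold, 1.59–4.73) were higher in TMREhi, while the antioxidant list had 10 higher and 7 lower (median 0.12, −0.10 to 0.70). Immediate early genes (median −0.67, −1.06 to 0.15) and p53 targets (median −0.67, −0.93 to 0.19) had intervals that included 0. The early response gene Jund was 3.22-fold higher in TMRElo (2.27–4.46).

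Further genes with large ratios included Ramp1, a co-receptor for the neuropeptide CGRP (228 against 57.1 CPM; 3.996-fold higher in TMREhi, 1.83–10.9), and Fabp5, a fatty acid carrier (3.36-fold, 1.62–8.39). Themis, a receptor signalling regulator of thymocytes, was 4.11-fold higher in TMRElo (2.92–5.66; 102 against 419 CPM), and Tnfrsf9, a costimulatory receptor, 8.03-fold (5.03–12.4), with 51.9% of its TMRElo UMIs in 1 cell. In GRCm38 coordinates the main genes were Maf (ENSMUSG00000055435, chromosome 8, 115682942–115707794), Blk (ENSMUSG00000014453, chromosome 14, 63372836–63417037), Sox13 (ENSMUSG00000070643, chromosome 1, 133382303–133424377) and Trdv4 (ENSMUSG00000076867, chromosome 14, 54074905–54075515). Also reported were Gzma (ENSMUSG00000023132, chromosome 13, 113093825–113100981), Xcl1 (ENSMUSG00000026573, chromosome 1, 164931644–164935527), S1pr1 (ENSMUSG00000045092, chromosome 3, 115710433–115715072), Foxo1 (ENSMUSG00000044167, chromosome 3, 52268336–52353221), Stat4 (ENSMUSG00000062939, chromosome 1, 51987148–52107189), Uqcrq (ENSMUSG00000044894, chromosome 11, 53427922–53430831) and Cd24a (ENSMUSG00000047139, chromosome 10, 43578284–43584265).

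Markers of αβ lineage thymocytes, led by the β chain constant genes Trbc1 and Trbc2, summed to 2349 CPM in TMREhi and 2075 CPM in TMRElo. Markers listed for γδ T cells summed to 3917 and 5015 CPM. Cd3d, Cd3g and Cd3e, which αβ T cells also express, led that list with 2737, 2392 and 1761 of 11381 UMIs in TMREhi. In TMRElo they had 98, 139 and 116 of 527 UMIs. The sums therefore do not rank the 2 lineages. Granulocyte and mast cell markers were Cpa3, a mast cell protease gene, alone (123 CPM against 9.52 CPM, 1 UMI). Summed macrophage markers gave 449 CPM in TMREhi and 305 CPM in TMRElo (all from Tyrobp, an adaptor also used by NK cells), markers of innate lymphoid and NK cells 294 and 495, and B cell markers 175 and 352. Erythroid markers had no UMI in retained cells of either library. Scrublet called 6 TMREhi (0.499%) and 8 TMRElo barcodes (4.08%) of all deposited as doublets, of which 3 and 2 were among the retained cells.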

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

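The tests of IL-17 genes against cell cycle and few UMIs, and of Xcl1 against a single cell, were chosen only after their results had been seen. The others were written down before their values were computed.

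Globin UMIs were found in data that the comparison leaves out. Among the 63 TMRElo barcodes with fewer than 500 genes they reached 7277 CPM (6272–8399), all 187 of them in 1 barcode with 209 UMIs and 21 genes. The 177 TMREhi barcodes under 500 genes held none.

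The IL-17 programme list stood higher in TMREhi, and other sources of this difference were weighed. A different share of low-ribosomal barcodes is not a likely source, since the list median within that class was 1.90 (1.14 to 2.65), or 0.83 with members at 0 UMIs set at their bound. More cycling cells in TMREhi is not one either, since within TMREhi the list's CPM in S or G2/M cells was 0.303 (0.270–0.340) of that in G1 cells. Nor are the αβ lineage thymocyte-like barcodes, since the median without them was 2.48 (1.69 to 3.25), or 1.36 with bounds. Few TMRElo UMIs for most members leave the size of the ratios uncertain. Clustering of barcodes with at least 500 genes, chosen after the counts had been seen, argues against few UMIs as the only source. A cluster led by Il23r, with Il1r1 among its leading genes, held 99 of 1025 TMREhi and 0 of 133 TMRElo barcodes. A cluster with Sox13 among its leading genes held 150 and 2. The first had a median of 1208 UMIs, near the 1113 of TMRElo barcodes. A true difference between the sorted fractions and a difference between the 2 preparations remain open, and only more libraries could separate them.

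The nuclear oxidative phosphorylation list also stood higher in TMREhi. A different share of low-ribosomal barcodes alone is unlikely to account for all of it. The median was 1.06 (0.82 to 1.16) within that class and 0.27 (0.21 to 0.44) among high-ribosomal barcodes. The latter is well below the 0.51 of retained cells. Ribosomal content still differed inside the low-ribosomal class, at 6.35% of UMIs in TMREhi and 3.54% in TMRElo. The cytosolic ribosomal protein list had similar medians, 0.86 in that class and 0.28 among high-ribosomal barcodes. The split therefore cannot decide whether the list follows ribosomal content. More cycling cells might account for the list difference, since the median among G1 cells was 0.11 (−0.03 to 0.30). That median still stood at the 98.5 percentile of matched random lists, so it was not that of an average list. The list's CPM in TMREhi was 25056 in G1, 31145 in S and 30274 in G2/M cells. Against this, the list in TMRElo had 25310 CPM in G1 and 24488 CPM (21585–27672) in S, so S cells still differed between the libraries (30359–31947 in TMREhi). With 8 TMRElo cells in G1 and 5 in S, this explanation stays open, as does a true difference in membrane potential and respiratory gene expression together.

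Xcl1 stood higher in TMRElo, where 1 cell held 73.6% of its UMIs. That cell alone could not account for the difference, since without the top cell of each library the TMREhi over TMRElo ratio was 0.0828 (0.0652–0.106), although in G1 cells the direction turned (157 against 1 UMIs). The labels describe a sort of γδ T cells, which would leave out innate lymphoid and NK cells. Carry-over of such cells could still be a source, and of 8 TMRElo barcodes with at least 2 Xcl1 UMIs 62.5% (24.5–91.5) held both CD3 and V segment UMIs, against 72.8% of the other barcodes, too few to decide. The top cell held 17 Cd3g and 3 Trdc UMIs, and also 3 UMIs of Kit, which is among the markers of innate lymphoid and NK cells. It held none of Ncr1 or Klrb1c, but the whole TMRElo library had 0 Ncr1 and 8 Klrb1c UMIs, so their absence decides little.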

How the results depend on the processing

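The barcode class, 25% mitochondrial limit and top-cell settings, V segments over all deposited barcodes, clustering of barcodes with at least 500 genes and the rule that named clusters of other types were chosen only after the counts had been seen, and all others before the data were examined. Across settings 239 list medians stayed within the interval of retained cells, 93 left it and 4 reversed. Among log2 ratios of genes these numbers were 517, 111 and 17, of which many had 0 TMRElo UMIs, and among shares 37, 51 and 3. No paired analysis was possible because each group had 1 library. Depth limited TMRElo, where 3 UMIs stood at 28.5 CPM. Unless stated, the cause was not tested for any value below, and percentages of V segments are of γ or δ UMIs.

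With all deposited barcodes the list medians were −1.49 for the IFN-γ programme, 0.94 for oxidative phosphorylation and 1.48 for G2/M. The mitochondrial share in TMREhi minus TMRElo was −3.74 points, and V segment shares were 59.2% and 33.6% for Trdv4 in TMREhi and TMRElo, with 9.55% for Tcrg-V6, 16.5% for Tcrg-V4 and 51.0% for Trgv2 in TMREhi. With the stricter filter the IFN-γ median was −1.71, oxidative phosphorylation 0.27 and G2/M 0.21, and S phase reversed to −0.0814. The mitochondrial difference (0.0142 points) also reversed. Egr2 (2.14) and Tnfrsf9 (5.12) had log2 ratios of the other sign only because TMRElo had 0 UMIs, with TMREhi below the 3-count floor of 48.6 CPM, so no direction can be read. IL-17 with members at their bound was 0.25 under that filter. A 5% mitochondrial limit alone gave a difference of 0.0826 points, but like the stricter filter it caps the share compared. A 25% limit gave −1.61 for IFN-γ, 0.84 for oxidative phosphorylation and 1.46 for G2/M. Without clusters of other types G2/M was 0.68.

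With G1 cells only, the medians were 5.67 for IL-17 (0.00477 with members at their bound), −0.0765 for IFN-γ, 0.11 for oxidative phosphorylation, −0.30 for S phase (reversed) and 0.58 for G2/M. There 8 TMRElo cells were left and 3 counts stood at 95.8 CPM. The log2 ratios of Cd44 (5.28), Egr2 (2.15), Ccl4 (2.98), Gzmc (3.71), Gzmb (6.09) and Tnfrsf9 (5.52) came from 0 TMRElo UMIs with TMREhi below that floor, so no direction can be read. Xcl1 (3.04; interval of the ratio 1.50–337) and Neat1 (0.42; 0.221–55.4) had 1 TMRElo UMI each, and Trdc was 0.37 on 10 TMRElo UMIs, with an interval of the ratio of 0.689–2.72. Means of per-cell CPM gave −1.60 for IFN-γ, 0.82 for oxidative phosphorylation and 1.72 for G2/M. Thinned cells gave 5.46 for IL-17 (0 with 18 of 25 members at their bound), 0.28 for oxidative phosphorylation and 1.28 for G2/M (0.55 with bounds), and Neat1 (5.13) had 0 TMRElo UMIs with TMREhi below the floor of 95.3 CPM. The other denominator gave −1.84 for IFN-γ and 0.66 for oxidative phosphorylation, and centred ratios −1.79 and 0.70. Members of at least 50 CPM gave 0.33 for IL-17, with fewer genes in the list by construction, and without the top cell Cd44 reversed to 0.27.

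Low-ribosomal barcodes gave −0.65 for IFN-γ, 1.06 for oxidative phosphorylation, 0.24 for mitochondrial mRNAs (reversed) and 2.51 for G2/M, with Ccl4 at 1.34 on 0 TMRElo and 2 TMREhi UMIs, a mitochondrial difference of 3.003 points (reversed) and 85.8% of TMREhi cells in S or G2/M. Their V segment shares in TMREhi and TMRElo were 64.2% and 42.7% for Trdv4, 12.7% and 1.18% for Tcrg-V6, and 20.7% and 28.6% for Tcrg-V4, with Trgv2 at 41.7% in TMREhi. Without αβ-like clusters they gave 2.48 for IL-17, −0.10 for IFN-γ, 0.88 for oxidative phosphorylation, 0.34 for mitochondrial mRNAs (reversed) and 1.86 for G2/M, and Ndufv2 (−0.0822) and Gzmb (0.55) reversed, both with 7 TMRElo UMIs and intervals of the ratio that held 1. Ccl4 (1.76) again had 0 TMRElo UMIs. High-ribosomal barcodes gave 0.27 for oxidative phosphorylation, 0.51 for G2/M and a mitochondrial difference of −0.558 points. Counting cells by their most abundant segment gave, in TMREhi and TMRElo, 35.4% and 0% for Trdv4, 16.1% and 0% for Tcrg-V6, 9.74% and 27.6% for Tcrg-V4, and 59.6% for Trgv2 in TMREhi. Cells of other types were 0% in both libraries at clustering resolution 0.5, and 25.5% and 0% among barcodes with at least 500 genes.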

Other observations

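The summaries by barcode in this part, including those of macrophage, Rag1 and αβ-like clusters, were chosen only after the counts had been seen.

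The macrophage genes Lyz2, C1qa, C1qb, C1qc, Apoe, Cd68 and Csf1r were concentrated in few TMREhi barcodes, with 1000 of 1145 UMIs in 4 barcodes, of which 3 were retained. They had no UMI in TMRElo. Rag1 had at least 1 UMI in 299 TMREhi barcodes and in 1 TMRElo barcode. The αβ-like barcodes had γ or δ V segment UMIs in 30.7% of cases (25.1–36.6), a share that the rule naming these clusters held below 50%, against 84.7% of the other low-ribosomal TMREhi barcodes and 88.9% of the TMRElo ones. They also held Cd4 at 279, Cd8a at 328, Ptcra at 196.5 and Trdc at 148 CPM, against 7.41, 193, 0 and 852 CPM in the low-ribosomal TMRElo barcodes, so Cd8a set them apart less than Cd4.

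The neighbouring mitochondrial genes mt-Atp8 and mt-Atp6, which encode ATP synthase subunits, differed in direction among retained cells, with ratios of 1.35 (1.17–1.56) for mt-Atp8 and a log2 ratio of −0.71 for mt-Atp6. Among low-ribosomal barcodes without αβ-like clusters the ratios were 2.90 (2.69–3.12) and 1.11 (1.07–1.15). In those barcodes Pdcd1 stood at 122 against 7.41 CPM (19.7-fold higher in TMREhi, 3.46–783, on 1 TMRElo UMI) and Cd5 at 135 against 22.2 CPM (6.07-fold, 2.02–29.9). Ifng had 3 UMIs in total, all in 1 TMRElo barcode.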
